A study of Rosa hybrid cultivar with 10 samples.

How the data were processed

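The material was leaf RNA of a hybrid rose, sequenced as messenger RNA from 10 libraries: 2 of unsprayed leaves at 0 h and 2 each at 6, 12, 18 and 24 h after a spray with 200 mM indole-3-acetic acid. RNA was extracted with a Qiagen RNeasy kit and libraries were made with a SMARTer mRNA-seq kit, per the labels' protocols. Groups were taken from the labels and the column names. A count column of the 0 h group carries no replicate number and is called unsprayed_0h replicate unnumbered. Small RNA libraries of the study were not part of the files used here.

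The read counts per gene and library were deposited by the authors as whole numbers, per the file headers. The FPKM values were deposited by the authors beside the counts. They equalled count over gene length and library total within 0.1% for 92.6% to 92.8% of the genes with reads in the 9 FPKM columns checked. Among genes with reads, this held for 100% of those whose IDs are built on a contig name, but for 51.71% to 51.92% of those among the other 6822 IDs. The p-value and adjusted p-value columns come from the authors' deposited comparisons of pairs of groups, per the file headers. They were used only to set the authors' calls beside those made here. The aligner, the genome build, the counting program and the program behind those p-values are not given in the sources used here. 1 further FPKM column, whose replicate number has no count column beside it, was not used.

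The deposited table held 74202 genes on 24505 contigs of a draft assembly, of which 67380 carry IDs built on a contig name and 6822 carry other IDs. Of all genes, 23714 had no reads in any library. Descriptions came from the deposited annotation: 42374 genes had a Swiss-Prot description, 4805 a description from NCBI nr alone and 27023 none. The species of the assembly is not given in the sources used here and may differ from the hybrid sampled. A draft assembly can hold near-identical copies of many genes. How the authors' counting split reads between copies is not given in the sources used here, so values of single copies are uncertain. The counting is not stated to use strand.

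Library totals ran from 15378942 to 18383638 reads. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the groups, which left 34942. Libraries were scaled by trimmed mean of M values factors. A quasi-likelihood model with 1 term per group was fitted to the 10 libraries, with 5 residual degrees of freedom and a common biological coefficient of variation of 0.175. Each time was compared with 0 h, and each time from 12 h on with the time before it, by two-sided quasi-likelihood F-tests. A joint F-test covered the 4 contrasts against 0 h. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called below an adjusted p of 0.05 with no minimum fold change. The standard error of a log2 fold change is its size over the square root of F. Of the genes tested, 13774 had an unadjusted p under 0.05 at 6 h.

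The groups, tests, gene lists and alternatives were chosen before the data were examined, except where a test or alternative is said to have been chosen later. There were 31 gene lists, matched by product description and gene symbol. The auxin lists held Aux/IAA repressors, GH3 conjugating enzymes, SAUR genes, auxin response factors, TIR1/AFB receptors, auxin transport, auxin synthesis and breakdown, and LOB domain genes. The hormone lists held ethylene synthesis, abscisic acid metabolism with PP2C phosphatases, ethylene-responsive factors, cytokinin genes, gibberellin oxidases, and jasmonate synthesis with JAZ. The other lists held expansins with xyloglucan endotransglucosylases, photosystem and light-harvesting proteins, circadian clock genes, heat shock proteins, glutathione S-transferases, UDP-glycosyltransferases, pathogenesis-related proteins, flavonoid synthesis, lignin synthesis, cell cycle and replication, families targeted by conserved microRNAs, and senescence. Lists of xylem, phloem, epidermis with guard cells and trichomes, other organisms, and organelle-encoded and ribosomal transcripts served as checks on tissue and RNA. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 124 tests (31 lists at 4 times), and again with an estimated correlation. Of the 124 tests 48 passed with the preset correlation and 0 with the estimated one, where the lowest adjusted p was 0.303. List tests between neighbouring times were chosen after the data were seen, since the plan held list tests against 0 h alone, and were adjusted over their own lists and 3 contrasts.

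Genes were named by rule. For each time against 0 h, the rule took the 5 largest rises and 5 largest falls among called genes with both replicates beyond both 0 h libraries, a mean of at least 5 CPM and an informative description, with 1 gene per description. For each auxin, ethylene synthesis and abscisic acid list it took the 2 members with the smallest p at each time, and for other lists the same where the list test passed. For neighbouring times it took the 3 largest rises and falls. The text gives a selection of the genes so named. A gene with no reads in a group was set against a floor of 3 counts over the group, and a gene with 1 to 3 reads was given a 95% exact (Clopper-Pearson) interval of the ratio.

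The overlap of calls between times was set beside that of independent lists, and the covariance of fold changes beside 10 draws of simulated unchanged groups sharing 2 controls. Enrichment of 891 gene ontology terms of 20 to 500 genes was tested by one-sided Fisher exact tests among 16696 annotated genes, which was chosen after the data were seen. The pipeline was tested on counts simulated for the 6 h against 0 h comparison over 33128 genes, of which 200 were changed. edgeR recovered 6% of 67 genes changed 1.5-fold, 23.9% of 67 changed 2-fold and 81.8% of 66 changed 4-fold, with 5 calls among 32928 unchanged genes. DESeq2 1.42.0 recovered 22.4%, 38.8% and 87.9%. In limma's camera a planted list passed and a random list did not. Genes were simulated as independent of each other, so this says nothing about list tests on correlated genes.

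Alternatives were RLE factors, no count filter beyond 1 count, a filter of at least 5 CPM in at least 2 libraries, DESeq2, a fit to the 2 groups compared alone, a replicate block, an absolute log2 fold change of at least 1, limma-trend on log2(FPKM + 1) with FPKM recomputed from the counts by the same formula, and leaving out each library in turn. Chosen after seeing the data were leaving the 10 most abundant genes of any library out of the scaling, matching lists by description alone, and keeping 1 gene per description.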

Results

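Leaves of a hybrid rose cultivar were sampled before and after a spray with 200 mM indole-3-acetic acid (IAA), the main natural auxin and a growth hormone of plants. The concentration is that of the labels, which is high for a hormone spray and could not be checked in the sources used here. Messenger RNA was sequenced from 10 libraries in 5 groups of 2: unsprayed leaves at 0 h, and sprayed leaves 6, 12, 18 and 24 h after the spray. According to the labels, the series looked for transcripts and microRNAs tied to the control of transcription by auxin. Unsprayed leaves were sampled at 0 h alone, so the spray and the time since it changed together in every comparison with 0 h. The hour of the day changed with them, except perhaps at 24 h, as the hours of harvest are not given in the sources used here. The labels do not say whether the 2 libraries of a group came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

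The libraries held 16008437 and 16659921 gene-assigned reads at 0 h, 18383638 and 15695257 at 6 h, 15378942 and 16560301 at 12 h, 16422241 and 17053814 at 18 h, and 15704968 and 15441988 at 24 h. Between 42354 and 43610 genes had at least 1 read in a library, and 34942 genes passed the count filter and were tested. The 2 libraries of a group differed by more than counting noise, with a chi-square per gene of 6.43 to 9.32, a spread that library preparation alone can also give. Across genes, which are not independent replicates, the mean Pearson correlation of log2 levels with the 0 h libraries was 0.919 at 6 h, 0.919 at 12 h, 0.935 at 18 h and 0.959 at 24 h, beside 0.972 to 0.973 between libraries of a group. The 10 most abundant genes of each library took 12.11% and 11.81% of its reads at 0 h, 8.86% and 8.19% at 6 h, 4.64% and 4.9% at 12 h, 5.49% and 4.88% at 18 h, and 10.27% and 9.89% at 24 h. Levels below are normalised counts scaled to a library of 1e6 (CPM), given as mean ± SD (n = 2), and log2 fold changes are given ± SE. Genes are located by contig only, since the genome build is not given in the sources used here. Scaling by total counts in place of the trimmed mean would shift the median gene by 0.2 at 12 h and 0.18 at 18 h on the log2 scale. Intervals and floors for genes with few reads cover counting error only.

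Genes of the circadian clock, the daily timer of the plant cell, were among the largest rises and falls 6 h after the spray. GIGANTEA, a clock protein active in photoperiod sensing (GI, Rmu_sc0007258.1_g000001.1, positions 391 to 4525 of its contig, minus strand), rose from 0.46 ± 0.111 to 91.2 ± 8.14 CPM, a log2 fold change of 7.61 ± 0.18 (edgeR adjusted p = 4.7e-08). Adagio protein 3, a blue-light receptor F-box protein (ADO3, Rmu_ssc0000204.1_g000019.1), rose from 0.659 ± 0.212 to 149 ± 16.9 CPM (log2 fold change 7.81 ± 0.24, edgeR adjusted p = 1.22e-07), and the pseudo-response regulator APRR7 rose from 10.3 ± 0.644 to 372 ± 8.13 CPM. REVEILLE 7, a MYB-like factor of the clock family (RVE7, Rmu_co8458561.1_g000001.1, positions 1 to 1774 of its contig, plus strand), fell from 498 ± 2.2 to 8.65 ± 0.0629 CPM, a log2 fold change of -5.85 ± 0.12 (edgeR adjusted p = 1.91e-08). Of 47 clock genes tested, 17 rose, 18 fell and 12 did not pass, or 18 and 19 adjusted over the list alone, with a median absolute log2 fold change of 2.8. Their median was -0.03 (0.01 when libraries were scaled by total counts) and their mean 1.03, and the list stood above other genes (camera adjusted p = 0.00419), a call absent with an estimated correlation (adjusted p = 0.356) and without IAA_12h replicate 1 (0.504) or replicate 2 (0.534). With 1 gene per description the adjusted p was 0.517, and with genes of at least 5 CPM alone it was 0.162.

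Among the other named genes at 6 h, chlorophyll a-b binding protein 21, a light-harvesting protein (CAB21, Rmu_sc0004521.1_g000019.1), rose from 758 ± 3.13 to 13000 ± 1050 CPM (log2 fold change 4.1 ± 0.13, edgeR adjusted p = 1.41e-07). Fatty acid desaturase 4, a chloroplast lipid enzyme, fell from 240 ± 15 to 8.52 ± 1.65 CPM, and the zinc finger protein CONSTANS-LIKE 2 fell from 42.3 ± 6.44 to 1.75 ± 0.222 CPM. Pleiotropic drug resistance protein 1, a membrane transporter with no reads at 0 h, was at least 72.5-fold higher at 6 h, against a floor of 3 counts over the 0 h group. Heat stress transcription factor A-3 had 3 reads at 0 h and 666 at 6 h, a ratio of 207 (95% counting interval 70.6 to 1010), and Peroxidase 15 had 3 and 502 reads, a ratio of 156 (53.2 to 760). Scarecrow-like protein 6 was also among the 5 largest falls at 6 h (log2 fold change -5.04 ± 1.1, edgeR adjusted p = 0.00717), but its 0 h libraries differed widely (59.9 ± 75.7 CPM). The call was lost without IAA_6h replicate 1 (log2 fold change -4.78). The log2 fold change was -1.8 without unsprayed_0h replicate unnumbered and -5.96 without unsprayed_0h replicate 2.

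Genes of auxin signalling went both ways at 6 h. Of 27 Aux/IAA genes, which encode repressors of auxin-responsive transcription, 4 rose, 14 fell and 9 did not pass, with 4 and 14 adjusted over the list alone. The median log2 fold change was -0.7 and the list fell (camera adjusted p = 0.000457; adjusted p = 0.341 with an estimated correlation). Auxin-induced protein 22D (AUX22D, Rmu_ssc0000478.1_g000011.1) fell from 279 ± 10.1 to 90.8 ± 1.42 CPM (log2 fold change -1.62 ± 0.08, edgeR adjusted p = 7.13e-07), while an IAA27 gene (Rmu_sc0002525.1_g000008.1) rose from 76.4 ± 4.28 to 247 ± 26.1 CPM (1.69 ± 0.1, edgeR adjusted p = 2.35e-06). Another IAA27 gene (Rmu_sc0002270.1_g000025.1) fell from 162 ± 15.8 to 80.1 ± 1.23 CPM (-1.02 ± 0.12, edgeR adjusted p = 0.000144). Of 33 small auxin-up RNA (SAUR) genes, linked to cell expansion, 3 rose and 10 fell, or 3 and 11 adjusted over the list alone. An X10A-type SAUR (Rmu_sc0018437.1_g000009.1) fell from 23.6 ± 0.161 to 5.3 ± 0.323 CPM. The SAUR list fell with a median of -0.19 (camera adjusted p = 0.0459; adjusted p = 0.374 with an estimated correlation), and the call was lost without any 1 of 4 libraries, unsprayed_0h replicate 2, IAA_6h replicate 2 and both IAA_12h replicates (adjusted p 0.0516 to 0.0772). It was also lost with 1 gene per description (0.358) or with genes of at least 5 CPM alone (0.0627).

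Of 9 GH3 genes, whose products attach amino acids to IAA, 3 rose and none fell at 6 h, the same counts adjusted over the list alone. Their median log2 fold change was 0.35 and their mean -0.03, and the list test in limma's camera did not pass (adjusted p = 0.397). A GH3.5 gene (Rmu_sc0004044.1_g000003.1) rose from 447 ± 4.38 to 828 ± 82.8 CPM. Of 34 auxin response factor (ARF) genes 2 rose and 12 fell (2 and 13 adjusted over the list alone); ARF5 rose from 1.88 ± 0.677 to 16.6 ± 3.68 CPM and ARF9 fell from 74 ± 2.88 to 45.6 ± 2.21 CPM. The receptor TIR1 fell from 394 ± 2.79 to 286 ± 17.1 CPM, 1 of 2 of the 5 receptor genes that fell. The other was AFB3 (log2 fold change -0.22 ± 0.07), a call lost under DESeq2, without a count filter and without any 1 of the 4 libraries compared. Of 25 genes of auxin synthesis and breakdown, 9 rose and 5 fell (11 and 6 adjusted over the list alone), among them ILR1-like 1, a hydrolase that releases IAA from its conjugates (Rmu_sc0012443.1_g000011.1), which rose from 8.6 ± 1.78 to 103 ± 2.01 CPM. Of 8 auxin transport genes 1 rose and 3 fell (2 and 3 adjusted over the list alone), including an auxin transporter-like protein 2 gene that fell from 134 ± 1.84 to 55.9 ± 5.61 CPM. None of these last 4 lists passed the camera test.

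Jasmonate genes, which serve wound and defence signalling, rose as a list at 6 h, a call absent with an estimated correlation. Of 73 genes of jasmonate synthesis and of the JAZ repressors, 40 rose, 6 fell and 27 did not pass, or 41 and 7 adjusted over the list alone. The median log2 fold change was 1.04 (camera adjusted p = 4.79e-20; adjusted p = 0.303 with an estimated correlation). Linoleate 13S-lipoxygenase 2-1, which starts jasmonate synthesis (LOX2.1, Rmu_sc0000670.1_g000032.1), rose from 111 ± 8.55 to 617 ± 47.9 CPM (log2 fold change 2.47 ± 0.1, edgeR adjusted p = 4.91e-07), and another copy (Rmu_sc0009311.1_g000001.1) rose from 387 ± 38.9 to 3480 ± 535 CPM. Of 140 heat shock genes 44 rose and 9 fell, or 46 and 11 adjusted over the list alone (median 0.36, camera adjusted p = 0.000321; adjusted p = 0.303 with an estimated correlation); the heat shock cognate 70 kDa protein, a chaperone, rose from 79.2 ± 5.08 to 477 ± 23.1 CPM. Of 102 pathogenesis-related genes 38 rose and 4 fell, or 42 and 4 adjusted over the list alone (median 0.62, camera adjusted p = 0.000339; adjusted p = 0.31 with an estimated correlation). Glucan endo-1,3-beta-glucosidase 14 rose from 16.6 ± 0.299 to 270 ± 4.99 CPM and Pathogenesis-related protein 5 fell from 109 ± 4.37 to 41.6 ± 2.32 CPM.

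Of 28 genes of abscisic acid metabolism and its PP2C phosphatases, 11 rose and 5 fell at 6 h, or 14 and 7 adjusted over the list alone. The median was 0.49 (camera adjusted p = 0.00783; adjusted p = 0.303 with an estimated correlation). Protein phosphatase 2C 56 rose from 2.86 ± 0.531 to 39.9 ± 8.58 CPM, and abscisic acid 8'-hydroxylase 2, which breaks the hormone down, fell from 78 ± 11.7 to 17.3 ± 0.554 CPM. Of 68 photosystem and light-harvesting genes 21 rose and 15 fell (23 and 20 adjusted over the list alone). Their median was -0.14 and their mean 0.47, and the list test was upward (camera adjusted p = 0.00924; adjusted p = 0.663 with an estimated correlation). In the same libraries, the list of organelle-encoded and ribosomal transcripts, kept as a sign of RNA quality, fell in 20 of 35 genes and rose in 1 (21 and 1 adjusted over the list alone; median -0.71, camera adjusted p = 7.77e-08; adjusted p = 0.303 with an estimated correlation). The genes that fell were mostly described as ycf39, ycf45 or ycf36 or as subunits L to U of the chloroplast NAD(P)H-quinone oxidoreductase, the subunits being looked up after the values were seen. Many of these are nuclear genes in plants and not organelle transcripts. Phloem markers rose in 7 of 24 genes and fell in 1, also adjusted over the list alone (median 0.08, camera adjusted p = 0.0163; adjusted p = 0.374 with an estimated correlation). Protein SIEVE ELEMENT OCCLUSION B, a sieve tube protein (Rmu_sc0004336.1_g000031.1), rose from 187 ± 16 to 1460 ± 123 CPM. In all, 5445 genes rose and 4768 fell against 0 h at 6 h, 2840 and 1823 of them by at least 2-fold.

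**Figure D1:**
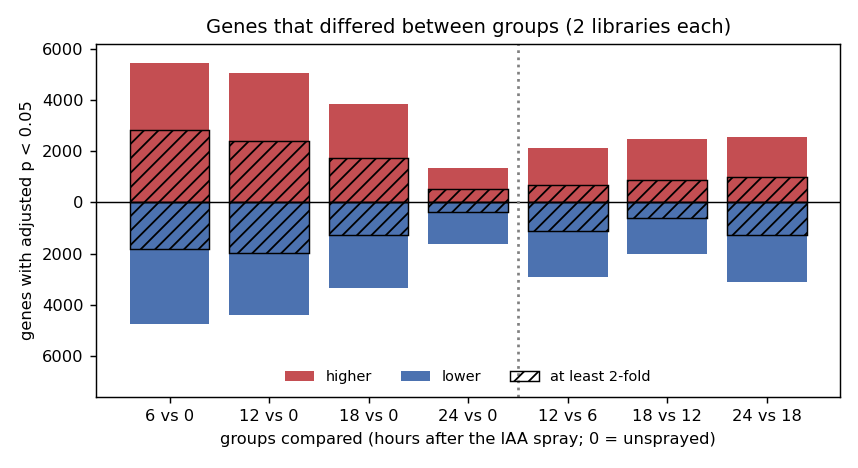
Genes with an edgeR adjusted p below 0.05 for each pair of groups, higher above 0 and lower below it, with hatching for changes of at least 2-fold; each group had 2 libraries. Calls against 0 h went from 10213 genes at 6 h to 2981 at 24 h.

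At 12 h single light-harvesting, clock and jasmonate genes were among the largest rises. Chlorophyll a-b binding protein 16 (CAB16, Rmu_sc0007661.1_g000008.1) rose from 1.33 ± 0.363 at 0 h to 444 ± 75.3 CPM (log2 fold change 8.36 ± 0.27, edgeR adjusted p = 2.06e-07), and GIGANTEA stood at 63.1 ± 4.19 CPM. Linoleate 13S-lipoxygenase 3-1 (LOX3.1, Rmu_sc0002145.1_g000002.1) rose from 1.26 ± 0.606 to 154 ± 44.5 CPM (6.94 ± 0.31, edgeR adjusted p = 6.47e-07). Early light-induced protein (Rmu_co8365229.1_g000001.1), a pigment-binding protein of light stress, fell from 21.6 ± 2.21 to 0.198 ± 0.194 CPM. Its log2 fold change was -6.68, but -5.97 without IAA_12h replicate 1 and -8.3 without IAA_12h replicate 2. CBL-interacting protein kinase 5, a calcium-signalling kinase (CIPK5, Rmu_sc0003242.1_g000007.1), fell from 400 ± 20.8 to 6.09 ± 8.18 CPM, and B-box zinc finger protein 32 fell from 156 ± 1.89 to 2.75 ± 3.71 CPM. Their 12 h libraries differed widely. The log2 fold changes of CIPK5 and B-box 32 were -6.01 and -5.79, -5.07 and -4.86 without IAA_12h replicate 1, and -10.32 and -10.23 without IAA_12h replicate 2. Pleiotropic drug resistance protein 1 was at least 365-fold higher than at 0 h. Of 47 clock genes 16 rose and 16 fell (17 and 17 adjusted over the list alone), with a median absolute log2 fold change of 2.3; the list test in limma's camera did not pass (adjusted p = 0.0642), although it passed without any 1 of the 4 libraries of 18 and 24 h (0.0234 to 0.0318). Of 68 photosystem and light-harvesting genes 10 rose and 27 fell at 12 h, or 11 and 29 adjusted over the list alone (median -0.22), and the list did not pass (camera adjusted p = 0.124), although it passed without IAA_12h replicate 1 (0.0413), unsprayed_0h replicate 2 (0.0365) or unsprayed_0h replicate unnumbered (0.0375).

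SAUR genes lay lower at 12 h: 2 of 33 rose and 13 fell, or 5 and 16 adjusted over the list alone. The median was -0.58 (camera adjusted p = 0.00783; adjusted p = 0.303 with an estimated correlation), and the X10A-type SAUR fell to 4.75 ± 0.541 CPM (log2 fold change -2.31 ± 0.15, edgeR adjusted p = 4.63e-06). Of the Aux/IAA genes 3 rose and 10 fell (5 and 10 adjusted over the list alone); 22D fell to 83.1 ± 2.63 CPM, whereas IAA26 (Rmu_sc0005201.1_g000009.1) rose from 65.2 ± 3.78 to 182 ± 16.8 CPM. Of the GH3 genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone. GH3.1 (Rmu_ssc0000481.1_g000001.1) rose from 6.01 ± 0.843 to 27.6 ± 4.69 CPM. ARF5 rose to 23.9 ± 4.19 CPM (log2 fold change 3.67 ± 0.28, edgeR adjusted p = 1.1e-05) and ARF9 fell to 30.6 ± 1.37 CPM, within an ARF list of 5 risen and 9 fallen genes (6 and 11 adjusted over the list alone; median -0.05, mean 0.06, and median 0.14 when libraries were scaled by total counts). Auxin transporter-like protein 3 rose from 22.2 ± 0.171 to 106 ± 7.46 CPM. Of the auxin transport genes 1 rose and 2 fell, and of those of auxin synthesis and breakdown 11 rose and 4 fell, the same counts adjusted over the list alone. The lists of Aux/IAA, GH3, ARF, transport and synthesis genes did not pass the camera test at 12 h, although GH3 passed without any 1 of the 6 libraries of 6, 18 and 24 h (0.0339 to 0.0441) and with genes of at least 5 CPM alone (0.0264).

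Of the jasmonate genes 38 rose and 8 fell at 12 h, or 38 and 9 adjusted over the list alone. The median was 1.06 (camera adjusted p = 3.26e-13; adjusted p = 0.352 with an estimated correlation). LOX2.1 stood at 965 ± 106 CPM (log2 fold change 3.12 ± 0.11, edgeR adjusted p = 2.43e-07), while 12-oxophytodienoate reductase 2 fell from 118 ± 2.51 to 24.6 ± 1.54 CPM. Of 43 senescence and chlorophyll breakdown genes 5 rose and 18 fell, or 7 and 19 adjusted over the list alone (median -0.49, camera adjusted p = 0.00783; adjusted p = 0.374 with an estimated correlation). STAY-GREEN LIKE, a chlorophyll breakdown protein, fell from 62 ± 0.78 to 12.4 ± 0.0175 CPM. Of the pathogenesis-related genes 29 rose and 6 fell, or 32 and 8 adjusted over the list alone (median 0.44, camera adjusted p = 0.0098; adjusted p = 0.374 with an estimated correlation). Of 93 UDP-glycosyltransferases 12 rose and 26 fell, or 14 and 27 adjusted over the list alone (median -0.17, and 0.03 when libraries were scaled by total counts; camera adjusted p = 0.0373; adjusted p = 0.374 with an estimated correlation); the call was lost without IAA_12h replicate 1 (0.144), IAA_12h replicate 2 (0.0579) or IAA_24h replicate 2 (0.0587). The organelle list fell in 15 genes and rose in 2, the same counts adjusted over the list alone (camera adjusted p = 0.000273; adjusted p = 0.374 with an estimated correlation). Phloem markers rose in 7 genes and fell in 1, or 8 and 1 adjusted over the list alone (median 0.45, camera adjusted p = 0.0242; adjusted p = 0.374 with an estimated correlation), a call lost with genes of at least 5 CPM alone (0.0778). In all, 5073 genes rose and 4420 fell at 12 h, and limma-trend on log2(FPKM + 1), which scales by total reads, gave 7760 and 3023.

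**Figure D2:**
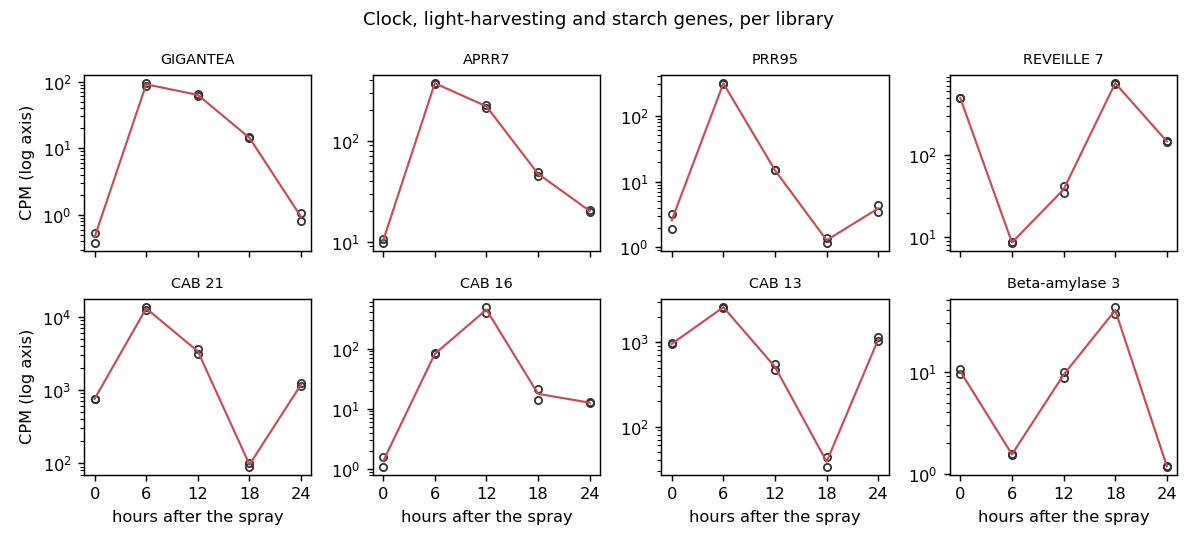
Normalised level in CPM on a log axis for 8 genes of the clock, of light harvesting and of starch breakdown against hours after the spray. Circles are single libraries and lines join group means. GIGANTEA peaked at 91.2 CPM at 6 h and was at 0.926 CPM at 24 h, beside 0.46 CPM at 0 h.

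At 18 h, light-harvesting genes lay below 0 h as a list, a call absent with an estimated correlation. Of the 68 photosystem and light-harvesting genes 5 rose, 43 fell and 20 did not pass, or 7 and 50 adjusted over the list alone. Their median log2 fold change was -0.8 (camera adjusted p = 1.02e-27; adjusted p = 0.303 with an estimated correlation). Chlorophyll a-b binding protein 13 (CAB13, Rmu_sc0001493.1_g000005.1) fell from 955 ± 22 to 38.4 ± 7.09 CPM (log2 fold change -4.64 ± 0.15, edgeR adjusted p = 4.6e-07), and CAB37 fell from 211 ± 20.1 to 12.9 ± 1.3 CPM. CIPK5 fell to 4.71 ± 0.512 CPM. LOX3.1 stood at 109 ± 9.4 CPM and 3-hydroxy-3-methylglutaryl-coenzyme A reductase 2, an enzyme of isoprenoid synthesis, rose from 0.296 ± 0.0582 to 14.6 ± 4.62 CPM. Pleiotropic drug resistance protein 1 was at least 114-fold higher than at 0 h, and Peroxidase 15 had 169 reads beside 3, a ratio of 48.3 (16.3 to 237). Of the clock genes 16 rose and 15 fell (17 and 15 adjusted over the list alone), with a median absolute log2 fold change of 0.8; the list stood higher (camera adjusted p = 0.0143; adjusted p = 0.374 with an estimated correlation), which was lost without IAA_12h replicate 1 (0.127) or replicate 2 (0.125) and with genes of at least 5 CPM alone (0.056).

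GH3 genes rose as a list at 18 h. Of 9, 4 rose and none fell, or 5 and 0 adjusted over the list alone, with a median of 0.84 (camera adjusted p = 0.00152; adjusted p = 0.303 with an estimated correlation). GH3.1 reached 59.1 ± 13.2 CPM, a log2 fold change of 3.3 ± 0.21 (edgeR adjusted p = 7.18e-06). Of the Aux/IAA genes 7 rose and 4 fell (7 and 5 adjusted over the list alone), and IAA26 rose to 238 ± 2.4 CPM. Of the SAUR genes 2 rose and 8 fell, also adjusted over the list alone (median -0.22, mean 0.1); SAUR32 fell from 127 ± 1.9 to 65.5 ± 3.33 CPM. Of the ARF genes 8 rose and 2 fell, or 9 and 2 adjusted over the list alone, and ARF4 rose from 22.3 ± 0.0646 to 48.6 ± 10.2 CPM. AFB3 fell to 108 ± 5.12 CPM and ILR1-like 1 stood at 127 ± 31.7 CPM. The Aux/IAA and SAUR lists did not pass limma's camera test, and the ARF list did not either (adjusted p = 0.0642). The ARF list passed without any 1 of 6 libraries, unsprayed_0h replicate unnumbered, IAA_18h replicate 1 and those of 6 and 24 h (0.0126 to 0.0498).

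Of 44 expansins and xyloglucan endotransglucosylases, enzymes that loosen and remodel the cell wall, 18 rose and 4 fell at 18 h, or 21 and 6 adjusted over the list alone. The median was 0.79 (camera adjusted p = 5.4e-06; adjusted p = 0.303 with an estimated correlation), and Expansin-like A1 rose from 1.55 ± 0.386 to 17.1 ± 0.461 CPM (log2 fold change 3.46 ± 0.21, edgeR adjusted p = 5.48e-06). Of the jasmonate genes 41 rose and 7 fell, or 48 and 7 adjusted over the list alone (median 1.12, camera adjusted p = 3.22e-29; adjusted p = 0.303 with an estimated correlation). Of 76 ethylene-responsive factors 20 rose and 6 fell, or 23 and 7 adjusted over the list alone (median 0.56, camera adjusted p = 0.00226; adjusted p = 0.303 with an estimated correlation); ethylene-responsive transcription factor 12 rose from 9.69 ± 0.205 to 40.3 ± 0.816 CPM. The ethylene call was lost with genes of at least 5 CPM alone (0.0627). The abscisic acid list had 11 risen and 6 fallen genes (13 and 6 adjusted over the list alone), with a median of 0.45, a mean of 0.24 and a downward test in limma's camera that did not pass (adjusted p = 0.974). A zeaxanthin epoxidase gene (Rmu_sc0001051.1_g000057.1) fell from 470 ± 38.3 to 124 ± 1.52 CPM. The other genes of that description rose or did not pass, and the most abundant of them rose from 9.5 ± 0.96 to 26 ± 3.88 CPM. In the same libraries the organelle list fell in 14 genes and rose in 2, or 16 and 2 adjusted over the list alone (camera adjusted p = 5.73e-05; adjusted p = 0.374 with an estimated correlation). Phloem markers rose in 6 and fell in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.379 with an estimated correlation), a call lost without unsprayed_0h replicate unnumbered (0.0819) or IAA_18h replicate 2 (0.136) and with genes of at least 5 CPM alone (0.0783). In all, 3862 genes rose and 3327 fell at 18 h, and limma-trend on log2(FPKM + 1) gave 6313 and 2234. The 7189 calls fell to 4721 without unsprayed_0h replicate unnumbered and to 4789 without unsprayed_0h replicate 2.

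**Figure D3:**
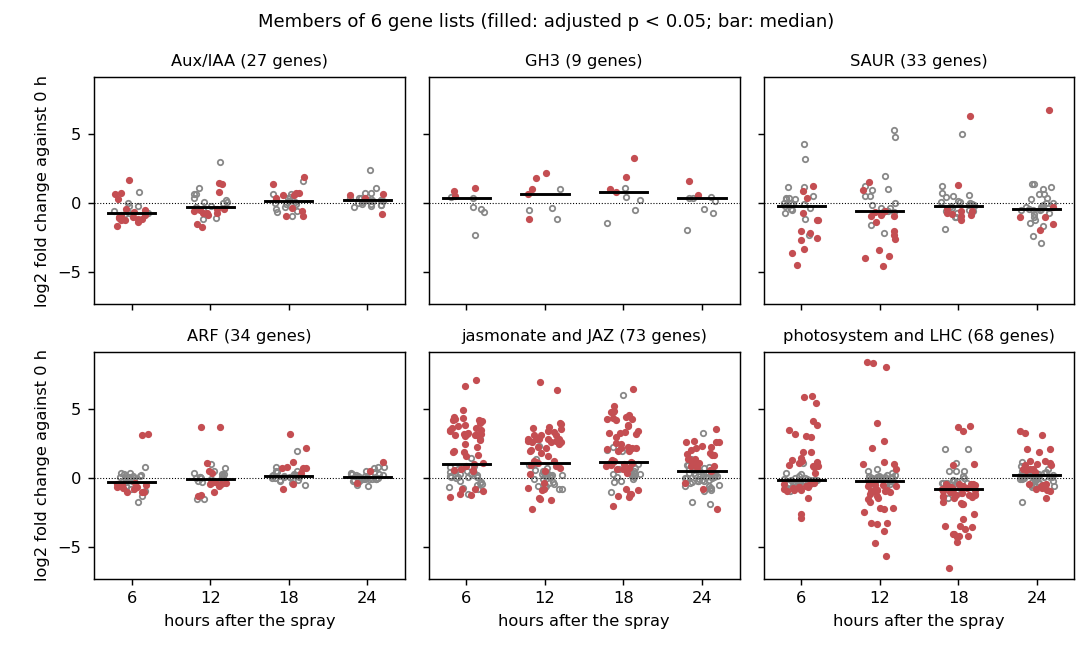
Log2 fold change against 0 h of each tested member of 6 gene lists at 6, 12, 18 and 24 h; filled red points have an edgeR adjusted p below 0.05 and bars are medians. Jasmonate medians lay at 1.04, 1.06, 1.12 and 0.52, and the photosystem median at -0.8 at 18 h.

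At 24 h, most clock genes did not pass the test against 0 h. A larger share of them was called than of all genes tested (8.5%). Jasmonate genes were still higher as a list (adjusted p = 0.303 with an estimated correlation). GIGANTEA stood at 0.926 ± 0.171 CPM beside 0.46 ± 0.111 CPM at 0 h (log2 fold change 1, edgeR adjusted p = 0.158). REVEILLE 7 remained lower at 148 ± 0.586 CPM (-1.75 ± 0.09, edgeR adjusted p = 1.65e-05) and APRR7 higher at 20.2 ± 0.762 CPM (0.98 ± 0.1, edgeR adjusted p = 0.00034). Of the 47 clock genes 2 rose, 7 fell and 38 did not pass, or 3 and 13 adjusted over the list alone (median -0.28, camera adjusted p = 0.0052; adjusted p = 0.352 with an estimated correlation), and their median absolute log2 fold change was 0.43. Of the jasmonate genes 25 rose and 3 fell, or 27 and 5 adjusted over the list alone (median 0.52, camera adjusted p = 5.88e-19; adjusted p = 0.303 with an estimated correlation). LOX2.1 was at 724 ± 20.8 CPM (2.7 ± 0.11, edgeR adjusted p = 1.89e-06).

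Arginase 1, an enzyme of arginine breakdown (ARGAH1, Rmu_sc0004624.1_g000006.1), rose from 6.65 ± 0.406 at 0 h to 90.3 ± 5.41 CPM at 24 h, a log2 fold change of 3.76 ± 0.11 (edgeR adjusted p = 3.18e-07). Gibberellin 2-beta-dioxygenase 8, which inactivates gibberellins (GA2OX8, Rmu_sc0000547.1_g000014.1), fell from 42.5 ± 9.95 to 1.85 ± 0.435 CPM (-4.51 ± 0.22, edgeR adjusted p = 7.78e-06). Early light-induced protein 1 fell from 476 ± 112 to 58.9 ± 2.22 CPM, and phenolic glucoside malonyltransferase 2 fell from 44.2 ± 0.807 to 5.23 ± 2.86 CPM. The log2 fold change of the latter was -3.08, but -3.78 without IAA_24h replicate 1. Sulfiredoxin, a thiol repair enzyme, and NUCLEAR FUSION DEFECTIVE 4 were the 2 largest rises by the naming rule, with log2 fold changes of 5.59 ± 1.38 and 3.83 ± 0.91 (edgeR adjusted p = 0.0361 and 0.0312). Both calls were lost without any 1 of the 4 libraries compared, with values of 4.92 to 6.75 and 2.91 to 6.64. Scarecrow-like protein 6 (-4.03 ± 1.02, edgeR adjusted p = 0.0413) lay at -0.8 without unsprayed_0h replicate unnumbered, and its call was also lost without either IAA_24h library (-4.41 and -3.73). The calls of 3-hydroxy-3-methylglutaryl-coenzyme A reductase 2 (3.64) and of a Beta-amylase 3 gene (-3.71) were lost without IAA_24h replicate 2 (3.12 and -3.42), the former also without either 0 h library (3.45 and 3.85) and the latter without IAA_24h replicate 1 (-4.07).

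Of the Aux/IAA, GH3 and SAUR genes 12 of 69 (17.4%) were called at 24 h, beside 8.5% of all genes tested. Of the Aux/IAA genes 3 rose and 1 fell, or 8 and 1 adjusted over the list alone. 22D remained lower at 166 ± 10.8 CPM, and the IAA27 gene that had risen at 6 h remained higher at 120 ± 9.14 CPM. The IAA27 gene that had fallen at 6 h did not pass (log2 fold change -0.25 ± 0.11). The list stood higher (median 0.2, camera adjusted p = 0.0373; adjusted p = 0.396 with an estimated correlation), a call lost without any 1 of 8 libraries, all but unsprayed_0h replicate unnumbered and IAA_24h replicate 2 (adjusted p 0.0541 to 0.168), with 1 gene per description (0.115) and with genes of at least 5 CPM alone (0.0727). Of the SAUR genes 1 rose and 5 fell, or 3 and 10 adjusted over the list alone (median -0.39, camera adjusted p = 0.00983; adjusted p = 0.303 with an estimated correlation). Of the GH3 genes 2 rose, also adjusted over the list alone: GH3.1 at 18.2 ± 2.06 CPM (log2 fold change 1.6 ± 0.21, edgeR adjusted p = 0.00168) and a GH3.5 gene at 184 ± 13.2 CPM. The GH3 list did not pass the camera test, although it passed without any 1 of 3 libraries and with genes of at least 5 CPM alone (camera adjusted p = 0.0225). Of the ARF genes 2 rose and 1 fell, also adjusted over the list alone, and none of the 5 receptor or 8 transport genes passed. The ARF calls named by the rule, ARF19 (0.49 ± 0.11) and ARF5 (1.15 ± 0.29), were each lost without IAA_24h replicate 1, IAA_24h replicate 2 or unsprayed_0h replicate 2, and ARF19 also without unsprayed_0h replicate unnumbered, with values of 0.44 to 0.55 and 0.82 to 1.35. IAA-amino acid hydrolase ILR1 rose from 36.7 ± 2.96 to 72.6 ± 2.47 CPM.

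Of the expansins and xyloglucan endotransglucosylases 12 rose and 2 fell at 24 h, or 15 and 4 adjusted over the list alone (median 0.4, camera adjusted p = 0.000566; adjusted p = 0.303 with an estimated correlation); xyloglucan endotransglucosylase/hydrolase 2 rose from 7.34 ± 0.388 to 25.2 ± 1.05 CPM. Of the photosystem and light-harvesting genes 17 rose and 9 fell, or 20 and 11 adjusted over the list alone (median 0.17, camera adjusted p = 0.000712; adjusted p = 0.565 with an estimated correlation), and CAB16 was at 12.6 ± 0.178 CPM. Of the abscisic acid genes 9 rose and 3 fell, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.0159; adjusted p = 0.303 with an estimated correlation), a call lost with 1 gene per description (0.113). Of 169 cell cycle and replication genes none rose and 19 fell, or 0 and 21 adjusted over the list alone (median -0.16, camera adjusted p = 0.00419; adjusted p = 0.374 with an estimated correlation); a histone H4 gene (Rmu_ssc0000309.1_g000047.1) fell from 89.4 ± 1.17 to 31.9 ± 0.15 CPM. The organelle list fell in 14 genes, or 15 adjusted over the list alone (camera adjusted p = 1.88e-09; adjusted p = 0.303 with an estimated correlation). Phloem markers rose in 2 of 24 genes, also adjusted over the list alone (camera adjusted p = 0.00353, and 0.352 with an estimated correlation), while 8.5% of all genes tested were called. The 2 were SIEVE ELEMENT OCCLUSION B at 1750 ± 29.2 CPM and PHLOEM PROTEIN 2-LIKE A9 (log2 fold change 0.53 ± 0.13). The call of the latter was lost without any 1 of the 4 libraries compared (log2 fold change 0.49 to 0.57). In all, 1368 genes rose and 1613 fell at 24 h. The 2981 calls fell to 1204 without IAA_24h replicate 2, 1351 without unsprayed_0h replicate unnumbered, 1593 without IAA_24h replicate 1 and 1598 without unsprayed_0h replicate 2.

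**Figure D4:**
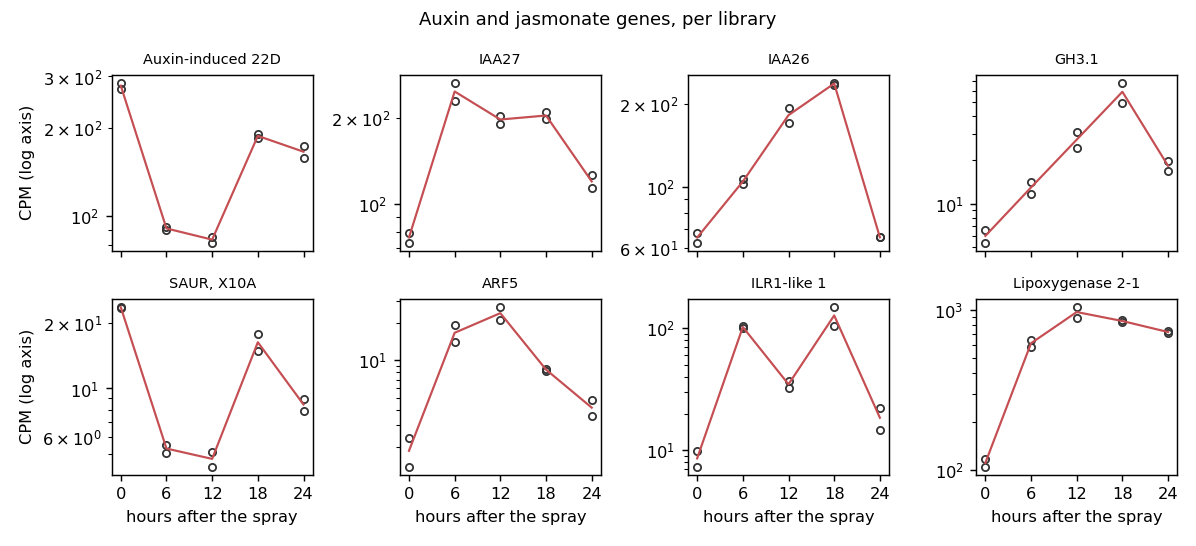
Normalised level in CPM on a log axis for 7 auxin genes and a lipoxygenase against hours after the spray; circles are single libraries and lines join group means. GH3.1 went from 6.01 CPM at 0 h to 59.1 CPM at 18 h, and lipoxygenase 2-1 was at 724 CPM at 24 h beside 111 CPM at 0 h.

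Between 6 and 12 h, light-harvesting genes fell and cell division genes rose as lists, calls absent with an estimated correlation (adjusted p = 0.392 and 0.148). Of 68 photosystem and light-harvesting genes 5 rose and 32 fell, or 8 and 34 adjusted over the list alone (median -0.39, camera adjusted p = 2.39e-11; adjusted p = 0.392 with an estimated correlation). Nerolidol synthase 1, a terpene synthase, fell from 464 ± 51.1 to 17.1 ± 5.14 CPM, a log2 fold change of -4.76 ± 0.25 (edgeR adjusted p = 1.11e-05), and the clock regulator PRR95 fell from 309 ± 12.9 to 14.8 ± 0.0347 CPM. Of 47 clock genes 5 rose and 16 fell, or 10 and 19 adjusted over the list alone (median -0.41, camera adjusted p = 0.0099; adjusted p = 0.307 with an estimated correlation). Beta-amylase 3, a starch-degrading enzyme (Rmu_co8257627.1_g000001.1), rose from 3.44 ± 0.352 to 25.8 ± 2.66 CPM. Of the cell cycle and replication genes 46 rose and 4 fell, or 50 and 4 adjusted over the list alone (median 0.41, camera adjusted p = 2.39e-11; adjusted p = 0.148 with an estimated correlation). Of the Aux/IAA genes 9 rose and none fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.000831; adjusted p = 0.246 with an estimated correlation). Of the heat shock genes 1 rose and 29 fell, or 2 and 33 adjusted over the list alone (camera adjusted p = 1.22e-05; adjusted p = 0.148 with an estimated correlation). List tests between neighbouring times were chosen after the data were seen. In all, 2120 genes were higher and 2905 lower at 12 h than at 6 h, and limma-trend on log2(FPKM + 1) gave 3804 and 1921. The 5025 calls fell to 2432 without IAA_12h replicate 1, 3044 without IAA_6h replicate 1 and 3077 without IAA_6h replicate 2.

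From 12 to 18 h, light-harvesting genes fell and Aux/IAA and SAUR genes rose as lists, calls absent with an estimated correlation (adjusted p = 0.204, 0.21 and 0.24). CAB21 fell from 3380 ± 438 to 95.8 ± 9.2 CPM, a log2 fold change of -5.14 ± 0.14 (edgeR adjusted p = 3.51e-07), and ethylene-responsive transcription factor ERF053 fell from 8.02 ± 1.4 to 0.145 ± 0.129 CPM. F-box protein PP2-B15 rose from 0.483 ± 0.425 to 19.9 ± 4.67 CPM (5.31 ± 0.42, edgeR adjusted p = 8.54e-05; 4.65 without IAA_12h replicate 1 and 6.7 without IAA_12h replicate 2). Of the photosystem and light-harvesting genes 3 rose and 25 fell, or 5 and 35 adjusted over the list alone (camera adjusted p = 1.96e-33; adjusted p = 0.204 with an estimated correlation). Of the Aux/IAA genes 10 rose and none fell, or 12 and 0 adjusted over the list alone (median 0.35, camera adjusted p = 5.35e-05; adjusted p = 0.21 with an estimated correlation). Of the SAUR genes 8 rose and 1 fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0268; adjusted p = 0.24 with an estimated correlation). In all, 2483 genes were higher and 2024 lower at 18 h than at 12 h. The 4507 calls fell to 2187 without IAA_12h replicate 1, 2545 without IAA_18h replicate 1, 2830 without IAA_18h replicate 2, and 2847 when the 2 groups were fitted alone.

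From 18 to 24 h, light-harvesting genes rose and jasmonate genes fell as lists, calls absent with an estimated correlation (adjusted p = 0.152 and 0.317). A cucumisin-like protease gene rose from 4.08 ± 0.391 to 304 ± 4.94 CPM (log2 fold change 6.22 ± 0.68, edgeR adjusted p = 0.000286) and CIPK5 rose from 4.71 ± 0.512 to 236 ± 19.7 CPM. Beta-amylase 3 (Rmu_sc0004987.1_g000004.1) fell from 39.9 ± 4.72 to 1.19 ± 0.0214 CPM (-5.05 ± 0.17, edgeR adjusted p = 7.79e-07). Of the photosystem and light-harvesting genes 39 rose and 2 fell, or 44 and 5 adjusted over the list alone (median 0.63, camera adjusted p = 3.29e-52; adjusted p = 0.152 with an estimated correlation). Of the jasmonate genes 6 rose and 32 fell, or 8 and 40 adjusted over the list alone (median -0.65, camera adjusted p = 4.12e-10; adjusted p = 0.317 with an estimated correlation). Of the GH3 genes 3 fell and none rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0099; adjusted p = 0.204 with an estimated correlation). In all, 2564 genes were higher and 3103 lower at 24 h than at 18 h, and limma-trend on log2(FPKM + 1) gave 1770 and 4772. The 5667 calls fell to 3237 without IAA_24h replicate 2, 3246 without IAA_24h replicate 1 and 3513 without IAA_18h replicate 1.

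Over the whole course 13665 of 34942 genes (39.1%) differed between 0 h and at least 1 later time in a joint edgeR test. The largest absolute change fell at 6 h for 3236 higher and 2234 lower genes, at 12 h for 2028 and 2335, at 18 h for 1453 and 1209, and at 24 h for 484 and 686. By calls against 0 h, 1429 genes were called in the same direction at all 4 times. Of the 1368 genes that rose at 24 h, 1011 (73.9%) had also risen at 6 h, and 1146 (71%) of the 1613 that fell had also fallen then. Independent lists would share 213.2 and 220.1 genes. Simulated unchanged groups set against shared controls gave at most 0.6 calls per draw, too few to gauge the overlap that shared controls add. Between 6 and 12 h, 3448 risen and 2877 fallen genes were shared, beside 790.5 and 603.1 for independent lists. The covariance of log2 fold changes between 6 and 12 h was 0.744 beside a simulated 0.0815 from the shared 0 h libraries, and between 6 and 24 h it was 0.367 beside 0.0812. The 0 h group was not split, as each part would keep 1 library, so part of each overlap may come from the shared controls.

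The authors' deposited table of comparisons called 3853 genes higher and 3237 lower at 6 h than at 0 h, of which 3748 and 3157 were called in the same direction here. A further 185 genes were called there alone and 3308 here alone. For 24 h against 0 h the authors' deposited table called 1047 and 1489, of which 924 and 1255 were shared. A further 357 were called there alone and 802 here alone. No gene called in the authors' deposited table was called in the opposite direction here in any of the 7 comparisons.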

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

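Among the tests below, the comparison of the jasmonate and clock lists at 24 h, the share of lower calls under total-count scaling and the list tests between neighbouring times were chosen after the result was seen, and the bounds of the other 3 tests of explanations were set before their values were computed. The tests of a daily rhythm take 24 h to be the same hour of day as 0 h, which the labels do not state.

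Gene groups whose medians lay on opposite sides of 0 h at neighbouring times were picked out where the difference between the times itself passed a test in limma's camera. Light-harvesting genes moved farthest: their median log2 fold change against 0 h was -0.8 at 18 h and 0.17 at 24 h, and the times differed (camera adjusted p = 3.29e-52; 0.152 with an estimated correlation). Cell cycle and replication genes went from -0.27 at 6 h to 0.19 at 12 h (2.39e-11; 0.148 with an estimated correlation) and from 0.07 at 18 h to -0.16 at 24 h (0.00129; 0.282). Cell wall genes of the expansin and xyloglucan endotransglucosylase list went from -0.07 at 6 h to 0.26 at 12 h (camera adjusted p = 2.56e-06, and 0.148 with an estimated correlation). Against 0 h, 9 of these genes rose and 11 fell at 6 h, and 15 rose and 5 fell at 12 h. Their list test against 0 h did not pass at 12 h. Aux/IAA repressors went from -0.29 at 12 h to 0.18 at 18 h (5.35e-05; 0.21), and auxin response factors from -0.05 (0.14 when scaled by total counts) to 0.17 between the same times (0.000917; 0.21). Clock genes went from 0.19 at 18 h to -0.28 at 24 h (1.1e-07; 0.148). Heat shock genes went from 0.03 at 12 h (0 with RLE factors) to -0.18 at 18 h (0 when scaled by total counts), with an adjusted p of 0.00121 (0.17 with an estimated correlation), and to 0.11 at 24 h (0.00611; 0.204). Xylem and secondary wall genes went from 0.57 at 12 h to -0.04 at 18 h (0.14 when scaled by total counts; adjusted p = 0.000851, and 0.521 with an estimated correlation). Only the light-harvesting and clock lists passed their tests against 0 h at both times of a pair. The Aux/IAA, auxin response factor, heat shock and xylem lists passed at neither, and the cell cycle list not at 12 or 18 h. A median beyond 0 h is thus not a tested change for those lists and times. None of these differences passed with an estimated correlation.

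Single genes called in opposite directions against 0 h at a pair of times, with the difference between the times called by edgeR, numbered 171 for 6 and 12 h, 329 for 6 and 18 h, 143 for 6 and 24 h, 130 for 12 and 18 h, 214 for 12 and 24 h, and 174 for 18 and 24 h. REVEILLE 7 was among them, at 498 ± 2.2 CPM at 0 h, 8.65 ± 0.0629 CPM at 6 h, 757 ± 18.7 CPM at 18 h and 148 ± 0.586 CPM at 24 h.

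Against 0 h, 10213 genes differed at 6 h, and fewer, 2981, at 24 h. A few abundant genes taking a changing share of the reads are argued against only as the sole cause, and may account for part of the pattern. The share of the 10 most abundant genes of each library was lower after the spray. With libraries scaled by total counts, that alone would leave other genes higher and not lower. Yet at least 26.1% of the calls at 6, 12 and 18 h were lower in limma-trend on FPKM. Most calls there were still higher, and at 12 and 18 h a larger share than with the trimmed mean. How much of the pattern this accounts for was not tested. The most abundant genes were not the same in every library, so the test is rough. A daily rhythm of the leaves may account for part of the pattern. The clock genes' median absolute log2 fold change at 24 h was 0.54 times the smallest of the earlier ones, between the bounds set for and against a rhythm. Rhythm and spray cannot be told apart, because unsprayed leaves were sampled at 0 h alone, and handling or the solvent of the spray stay open and untested for the same reason.

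Aux/IAA, GH3 and SAUR genes differed from 0 h in both directions. If a daily rhythm were the cause, few should differ a full day later, and 17.4% (12 of 69) were called at 24 h, between the bounds of 5% and 20% set beforehand. Of all genes tested 8.5% were called at 24 h, above the lower bound, so these bounds could not decide the question. Rhythm and auxin cannot be told apart for these genes, since no unsprayed leaves were sampled at the later times. A response to auxin is the biological difference the design names, and it could not be tested apart from time.

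Jasmonate genes were higher than at 0 h at all 4 times as a list, a call lost at each time with an estimated correlation (adjusted p = 0.303, 0.352, 0.303 and 0.303). Whether repeated copies of the same descriptions account for the median log2 fold change could not be decided. With 1 gene for each of 21 descriptions, the median was at least 0.85 times that of all 73 genes at each time. But the copy kept had the highest mean level over all libraries, most of them sprayed, which may favour copies that rose. Whether near-identical copies shared reads stays open, since the copy kept would still hold any shared reads. A daily rhythm stays open, with 34.2% of the jasmonate genes called higher at 24 h beside 9 of 47 clock genes called in either direction, and it cannot be told apart from the spray. Wounding or the solvent during spraying may also raise these genes, and no mock-sprayed leaves were sampled to test it.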

How the results depend on the processing

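Among the tests here, leaving out the most abundant genes, matching lists by description alone and keeping 1 gene per description were chosen after the data were seen. No named gene or list test passed in the opposite direction under the alternatives in which it was rerun. Named genes and lists were not retested in limma-trend on FPKM. Lists were also not retested with DESeq2, without a count filter or with the 2 groups compared alone. Scaling by total counts or RLE moved 9 list medians against 0 h to the other side of 0 or to 0. RLE factors, no count filter, a filter of at least 5 CPM, DESeq2, limma-trend on log2(FPKM + 1) and the replicate block kept each count of calls within 1.5 times: for 6 h, whose count was 10213, they gave 10218 (RLE), 9055 (5 CPM), 7874 (DESeq2) and 9849 (FPKM), and for 24 h, whose count was 2981, 2981, 3405, 2744 and 2956. An absolute log2 fold change of at least 1 left, by construction, 4663 genes at 6 h, 4360 at 12 h, 3024 at 18 h and 923 at 24 h against 0 h, 1776 for 12 h against 6 h, 1480 for 18 h against 12 h, 2272 for 24 h against 18 h, and 380 of the 1429 genes called in the same direction at all 4 times. Fitting 12 and 18 h alone gave 2847 calls in place of 4507, with fewer libraries to estimate the spread. With an estimated correlation 0 of the 48 list tests passed. Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 7347 to 7671 calls at 6 h, 6718 to 7114 at 12 h, 4721 to 5228 at 18 h and 1204 to 1598 at 24 h, 2432 to 3598 for 12 h against 6 h, 2187 to 3017 for 18 h against 12 h, 3237 to 3972 for 24 h against 18 h, 11671 to 12477 in the joint test, and 39 to 53 list tests; each such fit has fewer residual degrees of freedom, and other causes were not tested. Of 868 such refits of named genes 820 kept their side of the threshold, 47 lost and 1 gained a call, and of 1240 refits of lists 1176 kept it, 34 lost and 30 gained one. With genes of at least 5 CPM 12 list tests lost and 4 gained a call, and with 1 gene per description 6 lost and 5 gained one; the cause was not tested. Leaving the most abundant genes out of the scaling moved the median gene by at most 0.008 on the log2 scale, so it says nothing about the calls. RLE factors moved no named gene or list across the threshold, and DESeq2 moved 4 of 215 named genes. In limma-trend on FPKM, which scales by total counts, the share of higher calls went from 53.4% to 72% at 12 h, from 53.7% to 73.9% at 18 h and from 42.2% to 66.4% for 12 h against 6 h, and from 45.2% to 27.1% for 24 h against 18 h. Replicate numbers did not pair the libraries, since same-numbered libraries deviated together with a correlation across genes of -0.024 to 0.036. Here and in the replicate block, unsprayed_0h replicate unnumbered was taken as replicate 1 by elimination, which the column name does not state. With a replicate block the counts were 10027, 9330, 7080 and 2996 at 6, 12, 18 and 24 h, 4907, 4354 and 5602 for neighbouring times, 13184 in the joint test, 48 list tests and an overlap of 1469 genes. The pseudocount alternative planned for files without counts was not run, as counts were deposited. Depth limited genes with few reads: 3 counts over the 0 h group are 0.0982 CPM, and setting genes at 0 to that bound moved no list median by more than 0.09.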

Other observations

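Among the tests below, the gene ontology tests and the list tests between neighbouring times were chosen after the result was seen.

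Genes of phenylpropanoid metabolism, which makes flavonoids and lignin, were higher than at 0 h, the lignin list at all 4 times and the flavonoid list at 3 of them, calls that were all lost with an estimated correlation (adjusted p 0.374 to 0.514), and at 12 h the lignin call was also lost in 3 other alternatives given below. Dihydroflavonol 4-reductase, a step toward anthocyanins, rose from 123 ± 4.45 CPM at 0 h to 545 ± 14.7 CPM at 24 h (n = 2), a log2 fold change of 2.15 ± 0.13 (edgeR adjusted p = 2.52e-05), and flavonol synthase rose from 10.4 ± 0.092 to 70.2 ± 4.53 CPM at 6 h. Cinnamyl alcohol dehydrogenase 1, an enzyme of the lignin branch, rose from 3.55 ± 0.883 to 109 ± 4.57 CPM at 6 h (4.93 ± 0.23, edgeR adjusted p = 7.08e-07). Of 120 flavonoid genes 48 rose and 22 fell at 6 h (51 and 23 adjusted over the list alone; camera adjusted p = 0.0141, and 0.498 with an estimated correlation), 35 rose and 13 fell at 18 h (37 and 16; 0.021, and 0.514), and 16 rose and 8 fell at 24 h (24 and 13; 0.0184, and 0.505), while 12 h did not pass (0.644). The 18 h call was lost with genes of at least 5 CPM alone (0.0727). Of 146 lignin genes 41, 38, 31 and 16 rose and 10, 12, 6 and 1 fell at 6, 12, 18 and 24 h (43, 41, 34 and 17 and 10, 12, 6 and 1 adjusted over the list alone), with camera adjusted p of 0.00774, 0.0357, 0.00783 and 0.0143 (0.374, 0.451, 0.377 and 0.389 with an estimated correlation). The 12 h lignin call was lost without IAA_12h replicate 2 (0.0677), without unsprayed_0h replicate 2 (0.0896) and with genes of at least 5 CPM alone (0.0667), and the 24 h call without unsprayed_0h replicate 2 (0.102).

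Gibberellin oxidases and ethylene-responsive factors passed as lists at 6 h, the factors also at 18 h. Of 14 gibberellin oxidases 7 rose and 1 fell at 6 h (8 and 2 adjusted over the list alone; median 1.14, camera adjusted p = 0.0415, and 0.374 with an estimated correlation), and gibberellin 2-beta-dioxygenase 1 rose from 14.4 ± 2.8 to 49.9 ± 3.45 CPM. That call was lost without unsprayed_0h replicate 2 (0.0772), with 1 gene per description (0.318) and with genes of at least 5 CPM alone (0.347), and the later times did not pass (0.884, 0.869 and 0.884). Ethylene-responsive factors rose in 23 of 76 genes and fell in 9 at 6 h (25 and 9 adjusted over the list alone; camera adjusted p = 0.0297, and 0.374 with an estimated correlation), among them RAP2-7, which rose from 39.2 ± 3.47 to 224 ± 5.26 CPM. The call was lost without unsprayed_0h replicate unnumbered (0.0913) and with genes of at least 5 CPM alone (0.129). Of 7 ethylene synthesis genes at most 2 rose and 3 fell at any time (camera adjusted p 0.442 to 0.974), and of 27 cytokinin genes at most 7 rose and 6 fell (0.244 to 0.884). At 6 h 1-aminocyclopropane-1-carboxylate oxidase 1 rose from 306 ± 45.7 to 454 ± 8.76 CPM.

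Families targeted by conserved microRNAs, such as SPL, HD-ZIP III and GRF, were tested as a list. Of 121 such genes 20, 28, 26 and 11 rose and 17, 18, 6 and 6 fell at 6, 12, 18 and 24 h, and the list did not pass at any time (camera adjusted p = 0.658, 0.737, 0.0705 and 0.394), although it passed at 18 h without IAA_18h replicate 1 (0.024) or unsprayed_0h replicate unnumbered (0.0341). Small RNA levels were not available to set beside them. Of 11 LOB domain genes at most 3 rose and 1 fell at any time (0.466 to 0.884), and LOB domain-containing protein 38 rose from 17.3 ± 0.603 to 48.7 ± 18.1 CPM at 6 h. TIR1/AFB receptors did not pass as a list at any time (0.159 to 0.922), nor did auxin transport (0.199 to 0.486) or auxin synthesis and breakdown (0.117 to 0.616), although the last passed at 18 h without IAA_18h replicate 2 (0.044) and with 1 gene per description (0.036).

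Cell cycle and replication genes fell in 35 of 169 and rose in 7 at 6 h (34 and 7 adjusted over the list alone; median -0.27, camera adjusted p = 0.0163, and 0.374 with an estimated correlation), with kinesin-like protein KCA2 at 52.2 ± 1.78 CPM at 0 h and 27.5 ± 1.69 CPM at 6 h. At 12 h 37 rose and 14 fell and at 18 h 25 rose and 9 fell, without a list call (0.119 and 0.466). UDP-glycosyltransferases fell in 27 of 93 and rose in 13 at 18 h (30 and 14 adjusted over the list alone; 0.0184, and 0.374 with an estimated correlation) and fell in 12 and rose in 3 at 24 h (17 and 5; 0.0363, and 0.374). The 18 h call was lost without IAA_12h replicate 2 (0.0531), and the 24 h call without any 1 of 4 libraries, both of 12 h, IAA_24h replicate 1 and unsprayed_0h replicate 2 (0.0577 to 0.158), and with genes of at least 5 CPM alone (0.197). Pathogenesis-related genes rose in 26 of 102 and fell in 4 at 18 h (34 and 7 adjusted over the list alone; 0.0297, and 0.379 with an estimated correlation), which was lost without IAA_12h replicate 2 (0.0518), IAA_18h replicate 2 (0.119) or unsprayed_0h replicate 2 (0.0711), and 24 h did not pass (0.207). Glutathione S-transferases did not pass at any time (0.116 to 0.753); their median at 6 h was -0.01 (0.03 when scaled by total counts) and their mean 0.13. Heat shock genes did not pass at 12, 18 or 24 h (0.414, 0.219 and 0.124), although 24 h passed with 1 gene per description (0.0261).

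The lists kept as checks on tissue gave the following. Of 14 xylem and secondary wall genes 6 rose and 1 fell at 6 h and 6 rose at 12 h, without a list call (camera adjusted p = 0.0771 and 0.0883). The list passed at 6, 12 and 24 h without unsprayed_0h replicate unnumbered (0.00166, 0.00193 and 0.0263), and at 6 h without IAA_18h replicate 1 (0.0496). Of 26 epidermis, guard cell and trichome genes 10 rose and 4 fell at 12 h (12 and 4 adjusted over the list alone; 0.233), and the list did not pass at other times (0.124 to 0.856). At 6 h its median was 0.1, its mean 0.14 and its test downward. The list meant for other organisms matched 24 genes, of which the 8 tested are described as tobamovirus multiplication proteins or as polyproteins of a transposon, so it did not test for reads of other organisms; at most 1 rose and 1 fell at any time (0.443 to 0.834).

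Between neighbouring times, cell wall and flavonoid genes moved in both directions. Of the expansin and xyloglucan endotransglucosylase list 14 rose and 0 fell from 6 to 12 h (16 and 0 adjusted over the list alone; camera adjusted p = 2.56e-06, and 0.148 with an estimated correlation), 11 rose and 5 fell from 12 to 18 h (14 and 9; 0.000827, and 0.204), and 4 rose and 13 fell from 18 to 24 h (4 and 14; 0.0099, and 0.24). Gibberellin oxidases fell in 5 of 14 genes from 6 to 12 h and rose in 0 (5 and 1 adjusted over the list alone; 0.00142, and 0.24 with an estimated correlation), and 4 of 8 auxin transport genes rose and 0 fell (4 and 0; 0.000827, and 0.204). The list tests of the later pairs gave 0.959 and 0.927 for gibberellin oxidases and 0.927 and 0.0565 for auxin transport, and whether the pairs differ was not tested. Flavonoid genes fell in 24 and rose in 5 from 6 to 12 h (31 and 5 adjusted over the list alone; 0.00142, and 0.411 with an estimated correlation), and then 30 rose and 10 fell from 12 to 18 h (37 and 22; 0.0268, and 0.527).

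The other lists that passed between neighbouring times follow, each with the counts adjusted over the list alone, the camera adjusted p and that with an estimated correlation in brackets. From 6 to 12 h abscisic acid genes rose in 0 and fell in 7 (0 and 7; 0.000194, and 0.148 with an estimated correlation; median -0.13, and 0.03 when scaled by total counts), jasmonate genes rose in 4 and fell in 19 (9 and 24; 0.00142, and 0.529), senescence genes rose in 0 and fell in 8 (0 and 9; 0.0301, and 0.381), epidermis genes rose in 5 and fell in 1 (5 and 1; 0.0292, and 0.21), and organelle genes rose in 9 and fell in 2 (12 and 2; 0.035, and 0.527). From 12 to 18 h auxin response factors rose in 9 and fell in 1 (11 and 1; 0.000917, and 0.21 with an estimated correlation), ethylene-responsive factors rose in 12 and fell in 5 (16 and 8; 0.0409, and 0.387), jasmonate genes rose in 16 and fell in 3 (17 and 4; 0.000851, and 0.527), heat shock genes rose in 5 and fell in 28 (7 and 33; 0.00121, and 0.17), senescence genes rose in 11 and fell in 0 (15 and 4; 0.00473, and 0.259), and xylem genes rose in 0 and fell in 4 (0 and 8; 0.000851, and 0.521). From 18 to 24 h abscisic acid genes rose in 8 and fell in 4 (10 and 6; 0.0389, and 0.229 with an estimated correlation; median 0.1, and -0.04 when scaled by total counts), ethylene-responsive factors rose in 7 and fell in 19 (7 and 22; 0.0115, and 0.307), clock genes rose in 8 and fell in 16 (10 and 20; 1.1e-07, and 0.148), heat shock genes rose in 25 and fell in 8 (25 and 9; 0.00611, and 0.204), and cell cycle genes rose in 5 and fell in 34 (6 and 34; 0.00129, and 0.282).

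Gene ontology terms were tested among 16696 annotated genes, in 7128 tests of which 86 passed, with genes treated as independent although copies are near-identical. Genes annotated to the response to auxin were over-represented among those lower at 12 h, with 21 of 67 beside 9.5 by chance (Fisher exact adjusted p = 0.0319). Recognition of pollen held 49 of 178 genes lower at 12 h beside 25.3 by chance (0.00344). Siroheme synthesis held 27 of 66 genes higher at 6 h beside 11.6 (0.00442), glycolysis 27 of 79 genes higher at 12 h beside 13.2 (0.0214), and ammonium transport 13 of 26 genes lower at 12 h beside 3.7 (0.00804). At 24 h, lysine synthesis via diaminopimelate held 10 of 32 genes lower beside 1.8 (0.00436), and cellular glucan metabolism 15 of 107 higher beside 4.9 (0.0214).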
